A study of Mus musculus with 6 samples.

How the data were processed

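The data are RNA-seq libraries of mouse skeletal muscle, 6 in all, with 2 in each of 3 genotypes. Control mice carry floxed genes without Cre. LDKO mice lack the insulin receptor substrates Irs1 and Irs2 in the liver, where an albumin promoter drives Cre. LTKOFstL/L mice lack the follistatin gene Fst in the liver as well, per the series description. Total RNA was extracted with TRI Reagent and a SMARTer mRNA kit made the libraries, per the labels' protocols. The reference genome was mm10, per the submitters' processing notes. The aligner, the read counting, the normalization and the software are not given in the sources used here. The labels do not say that the 2 libraries of a group come from separate animals, so every p-value measures only the spread between these samples.

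The deposited table of all genes holds log2 values for 53342 Ensembl genes. As judged from the deposited values, the authors took the log2 of library-scaled read values with a floor at a scaled value of 1, and then centred each gene on the median of the 6 libraries. The largest absolute gene median in the table is 9.54e-07. Centring removes the absolute level of a gene, so values are comparable between libraries but not between genes. Where at least 2 libraries tie at the floor the level could be recovered exactly. For other genes it was bracketed from the rounding step of the stored single-precision numbers. On simulated tables the bracket was right for 84.7% of 22496 genes and for 92.2% of the genes that would be tested. Many values correspond to fractions of reads. Within a tolerance of 0.001, whole reads made up 55.2% and 55.4% of the values usable for this test in the Control libraries. The shares were 73.8% and 71.3% in LDKO and 55.8% and 58.1% in LTKOFstL/L, so read counts were not recovered. The LDKO libraries thus stand apart from both other groups, which the design does not separate from genotype.

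The total depth of a library is unknown, because the files give no read totals. Genes at the floor in 4 or more libraries show the scaled value of a single read, which was 2.12 and 2.03 units in the Control libraries, 1.81 and 1.76 in LDKO, and 2.12 and 2.11 in LTKOFstL/L. This value measures the scaling of a library, and depth cannot be read from it while the normalization is not given. Between 24027 and 24673 genes were above the floor in a library.

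The deposited lists of differential genes give p-values and corrected p-values that the authors obtained from an AC test, per the file headers, and log2 differences of group means. As judged from the values, these lists hold only genes with a corrected p under 0.05 and at least a 2-fold change. They were used for a count of shared genes only. The deposited table of group means and the pathway input repeat other tables and were not used here.

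Of the 53342 genes, 22929 were at the floor in every library and 30413 were detected in at least 1. The test took the 16323 genes whose log2 level was at least 4, or 16 scaled units, in at least 2 libraries. Of these, 16303 matched a gene of GENCODE M21, a mouse annotation on GRCm38, which supplied coordinates. A linear model with 1 mean per genotype was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, leaving 3 residual degrees of freedom. Variances were moderated with robust empirical Bayes, with a prior estimated separately in 3 strata of the level in the lowest library (log2 under 4, 4 to 8, and 8 or more). P-values were two-sided and adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The adjusted p is meant wherever a gene is said to have risen or fallen. Changes are differences of mean log2 values with the moderated standard error. In the lowest stratum the prior all but replaced a gene's own variance, and Ucp1, Eno1b, Rsc1a1 and Gm44364 share an SE of 1.274. Their p-values therefore rest on a spread pooled over genes.

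The groups, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The plan had been a variance trend over mean expression and a filter on mean value. Neither could be applied to centred values. The level filter and the level strata replaced them, and the strata were chosen after calls under other settings had been seen. They were compared on simulated tables modelled on LDKO against Control. On a table of 17188 genes without change the strata called 1 gene, a single prior called 0 and a spline trend over the level called 4, with 4.81%, 4.65% and 3.04% of genes at an unadjusted p under 0.05. A table of 17289 genes held 96 genes changed by log2 1 and 98 changed by log2 2. There the strata called 31.2% and 90.8% of these genes, a single prior 1% and 64.3%, and the spline 2.1% and 8.2%. Among the calls 7, 2 and 13 genes had not been changed, and no call had the wrong sign. In the real data the strata call many more genes than a single prior does.

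The rule for named genes takes the targeted genes, the 10 largest rises and the 10 largest falls per comparison among passing genes of at least median level whose groups do not overlap (unnamed gene models left out), the members of each list with the smallest p, and the genes changed in LDKO and moved back. Not every gene that meets this rule is named. Any other gene named was chosen after its values were seen. The level used for the second kind was the recovered or bracketed one.

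Gene lists numbered 26, and 25 had tested members; the list of mitochondrially encoded genes had 0, so it gives no result. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, two-sided, with adjustment over the 75 tests of 25 lists in 3 comparisons. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance one way, were alternatives. Both called 0 of the 75, where the preset correlation called 32. The estimated correlation ran from −0.031 for endothelial markers to 0.884 for Schwann cell and nerve markers. It was 0.333 for the atrophy list, 0.663 for slow fibre genes and 0.727 for adipocyte markers, all above the preset. Where it is higher, the preset gives p-values that are too small. Camera with an estimated correlation also refers its statistic to the 3 residual degrees of freedom, where small p-values are hard to reach. For fatty acid oxidation in LTKOFstL/L against LDKO the estimate was only 0.034, yet camera's unadjusted p went from 2.77e-08 to 0.0209. Its 0 calls among 75 tests are therefore weak evidence against a list, and do not measure the effect of correlation alone. The adjusted p of 0.736 recurs because the adjustment gives many tests the same value. For each list the members passing over all genes are given with those passing when "adjusted over the list alone". In 8 of the 75 tests, none of them a call, the median, the mean and the direction of the test differ in sign.

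Alternatives were a single prior, rescaling by the median ratio, no level filter, only the groups compared, the replicate number as a block, each library left out in turn, and a threshold of 0.10. Where 1 library of a group is left out, the remaining one is assumed to vary like the other groups. For a comparison without that group, the remaining library adds no spread to the gene tests. Leaving out either library of that group then gives the gene tests of only the groups compared, so these are not separate checks. Chosen after seeing the data were a spline trend, no robust moderation, a log2 level of at least 8, leaving out pancreatic acinar genes, and using 1 LDKO library in each comparison behind the genes moved back. Another pseudocount could not be tried, because the values are already centred logarithms. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.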

Results

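RNA from skeletal muscle was sequenced in 6 libraries of male mice, 2 each for the Control, LDKO and LTKOFstL/L genotypes. The sample labels give a high fat diet, while the series text gives chow from 5 to 16 weeks, so the diet is not settled by the sources. Values are centred log2 expression, and 16323 genes were tested. Total read depth is unknown. A single read weighed 1.81 and 1.76 scaled units in the LDKO libraries and 2.03 to 2.12 in the others. This measures the scaling and not the depth.

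The targeted genes were deleted in the liver, so their muscle transcripts do not check the labels. Irs1 (ENSMUSG00000055980, GRCm38 chromosome 1, 82233101 to 82291416), an adaptor of insulin receptor signalling, had mean log2 values of 0.19 ± 0.07 in Control, −0.22 ± 0.53 in LDKO and −0.27 ± 0.19 in LTKOFstL/L (SD, n = 2 each). None of its differences passed, with adjusted p of 0.819, 0.457 and 0.934 for LDKO against Control, LTKOFstL/L against Control and LTKOFstL/L against LDKO. Irs2 (ENSMUSG00000038894, chromosome 8, 10984681 to 11008458), its paralogue, fell by 2.31 ± 0.39 (SE) from Control to LTKOFstL/L (adjusted p = 0.0383). Its other differences were −0.86 for LDKO against Control (adjusted p = 0.773) and −1.45 for LTKOFstL/L against LDKO (adjusted p = 0.111). Neither passed, but both rest on unequal LDKO libraries. Irs2 in LDKO against Control passed at −1.55 without LDKO 2 (adjusted p = 0.00437) and stood at −0.17 without LDKO 1 (0.999). In LTKOFstL/L against LDKO it passed at −2.14 without LDKO 1 (adjusted p = 0.000986) and at −0.76 without LDKO 2 (0.0422). Fst (ENSMUSG00000021765, chromosome 13, 114452290 to 114458951), which encodes the activin and myostatin antagonist follistatin, was higher in LTKOFstL/L muscle than in LDKO muscle by 1.97 ± 0.36 (SE, adjusted p = 0.0353). The floxed segment covers exons 2 to 5, and the gene-level value does not separate exons. Fst differed from Control by −0.77 in LDKO (adjusted p = 0.773) and by 1.20 in LTKOFstL/L (adjusted p = 0.167). In LDKO against Control, Fst stood at −0.32 without LDKO 1 and −1.23 without LDKO 2, and Irs1 at −0.03 and −0.78, none of which passed. The Fst call stood without LDKO 2 (change 2.42) and was lost without LDKO 1 (1.51), LTKOFstL/L 1 (1.79) or LTKOFstL/L 2 (2.15). Leaving out a Control library gives the same fit as only the groups compared, listed below. The Irs2 call was lost without Control 1 (0.20), Control 2 (0.127), LTKOFstL/L 1 (0.16) or LTKOFstL/L 2 (0.17), and with a single prior neither passed (0.114 for Fst and 0.149 for Irs2). With no level filter neither passed (0.0625 for Fst and 0.0772 for Irs2). Fst was also lost with the replicate block (0.0528), with only the groups compared (0.0577) and with a spline trend (0.171). The Irs2 fall from Control to LTKOFstL/L stood in each of these settings (adjusted p = 0.0387, 4.76e-05 and 0.0327).

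LDKO against Control asks what the loss of both hepatic insulin receptor substrates does in muscle. Myh3, the embryonic myosin heavy chain, rose by log2 1.88 ± 0.18 (SE, n = 2 libraries per group, adjusted p = 0.00606). Casq2, the calsequestrin of slow and cardiac muscle, rose by 1.06 ± 0.14 (adjusted p = 0.0452). Chad, which encodes the cartilage matrix protein chondroadherin, fell by 1.79 ± 0.19 (adjusted p = 0.0113). Most other falls were in digestive enzyme genes of the exocrine pancreas, among them the elastases Cela3b at −11.00 and Cela1 at −8.48, the protease Ctrl at −10.64 and the carboxypeptidase Cpa1 at −10.48, each with an SE of 1.27. Of the 40 genes that fell, 25 stood on a list of 26 pancreatic acinar genes that was written after these values had been seen. The median acinar gene lay at 12.50 in Control 1 and 8.46 in Control 2, against 0.89 and −1.32 in the LDKO libraries and −1.77 and −1.68 in the LTKOFstL/L libraries. Of the 15 other falls, 12 were higher in Control 1 than in Control 2 by more than 3 on the log2 scale. Among these 12 were Cela3a, Try10 and Prss3, of the same enzyme families as listed genes. Chad, Gm10327 and Gm44364 lacked that gap. The 15 are also the falls that remain when the listed genes are left out, so that setting does not remove the whole pancreatic pattern. The 6 rises were Myh3, Casq2, BC048679, Eno1b, Gm6472 and Gm16505. Without the acinar genes 4 rises passed, since the adjustment depends on how many genes have a small p. Casq2 and Gm16505, which had the largest adjusted p of the 6 (0.0452 and 0.041), were then lost. In total 46 genes passed in limma, all with at least a 2-fold change, and 1097 had an unadjusted p under 0.05. The SE of the acinar genes comes from pooled variances and is smaller than their own spread in Control (SD 2.97 for Cela3b). Eno1b has the same pooled SE, with LDKO values of 4.58 and 1.80. Reads may be shared within the Try, Amy and Cela families. The count was 1 with a single prior, 2 with no level filter, 28 at a level of at least 8, 19 without the acinar genes (4 higher and 15 lower), 3 without Control 1 and 131 without LDKO 2. Of the 11 named genes that passed, 1 still passed without Control 1, 5 without Control 2, 9 without either LDKO library and 8 without either LTKOFstL/L library, and Gm6472 passed in all 6 of these fits.

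**Figure D1:**
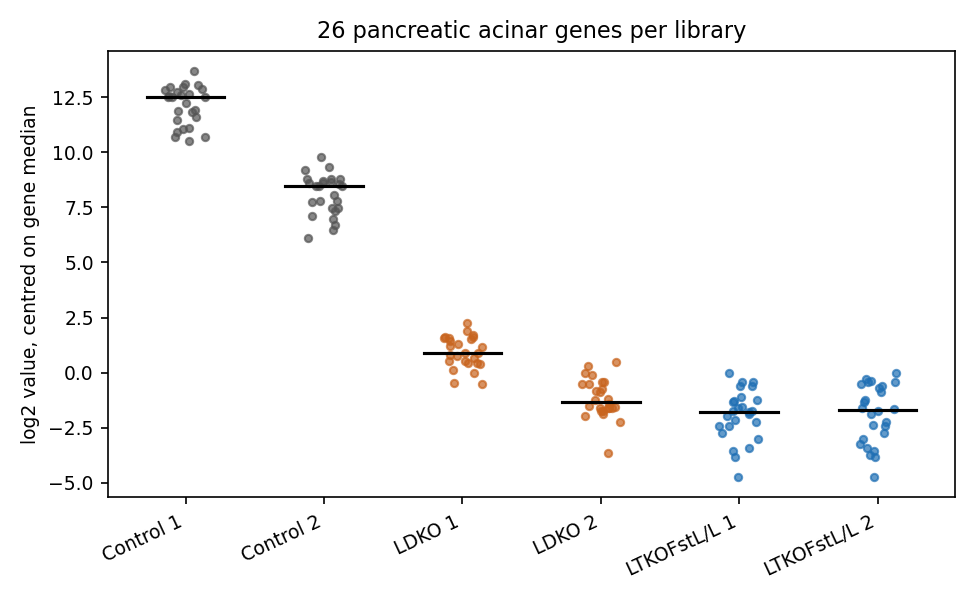
Centred log2 values of the 26 pancreatic acinar genes in each of the 6 libraries, with a black line at the median. The medians are 12.50 and 8.46 in the Control libraries and lie between −1.77 and 0.89 in the other libraries.

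All 14 slow fibre genes had higher means in LDKO than in Control, with a median log2 change of 0.64. Casq2 rose, though not once the acinar genes were left out, and 9 of the 14 rose when adjusted over the list alone. Myl6b at 1.23 (adjusted p = 0.182) and Tnni1 at 0.74 (adjusted p = 0.431) did not pass over all genes. The slow fibre list was called by camera (adjusted p = 1.03e-09), and adjusted p = 0.736 with an estimated correlation. Among 14 fast fibre genes the median was −0.01, 0 passed over all genes or adjusted over the list alone, and camera gave adjusted p = 0.646. The fast fibre list was called without LDKO 2 (adjusted p = 0.0476). Fatty acid oxidation genes (31 tested) had a median of 0.23, with 0 passing either way, and Decr1 at 0.58 and Fabp3 at 0.79 had adjusted p of 0.471 and 0.624. Camera called that list (adjusted p = 0.000229), and adjusted p = 0.736 with an estimated correlation. The 28 atrophy and FoxO genes had a median of 0.29, with 0 passing over all genes and 1 higher when adjusted over the list alone. The sestrin gene Sesn1 stood at 1.21 (adjusted p = 0.595). The atrophy list was called (adjusted p = 7.72e-05), with adjusted p = 0.736 under an estimated correlation, and it was not called without Control 2 (0.351). Oxidative phosphorylation genes (46 tested, 0 passing either way, median 0.14) were called at adjusted p = 0.00719, with adjusted p = 0.901 under an estimated correlation. That call was lost without Control 2 (0.332) and reversed in direction without LDKO 1 (0.803).

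Connective tissue and nerve lists had lower medians in LDKO muscle. The 11 fibroblast and tendon markers had a median of −0.53, with 0 passing over all genes and 5 lower when adjusted over the list alone. Kera, a corneal and tendon proteoglycan gene, stood at −2.65 (adjusted p = 0.195) and Tnmd, which encodes the tendon protein tenomodulin, at −1.21 (adjusted p = 0.311). Camera called the list (adjusted p = 1.65e-05), and adjusted p = 0.736 with an estimated correlation. The 11 Schwann cell and nerve markers had a median of −0.88, with 0 passing either way, and the myelin gene Mbp stood at −1.15 (adjusted p = 0.672). That list was called too (adjusted p = 2.51e-06), and adjusted p = 0.736 with an estimated correlation. The 29 extracellular matrix genes had a median of −0.17, with 0 passing over all genes, and 1 higher and 4 lower when adjusted over the list alone. Fmod at −0.97 (adjusted p = 0.183) and Postn at 1.84 (adjusted p = 0.263) went in opposite directions. The matrix list was called lower (adjusted p = 0.0131), with adjusted p = 0.746 under an estimated correlation. Without Control 2 it was not called (0.113), and without LDKO 2 its direction reversed (0.996). Macrophage and leukocyte markers (18 tested, 0 passing either way, median −0.44) were called at adjusted p = 0.00114, with adjusted p = 0.736 under an estimated correlation, and not without LDKO 2 (0.587). Smooth muscle and pericyte markers (10 tested, median −0.31, 1 lower when adjusted over the list alone) were called at adjusted p = 0.0169, with adjusted p = 0.736 under an estimated correlation. That call was lost without Control 2 (0.119) or LDKO 2 (0.313).

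Genes of activin, myostatin and BMP signalling, the family that follistatin binds, numbered 39 and had a median of −0.18 in LDKO against Control. None passed over all genes and 1 was lower when adjusted over the list alone. Smad3, a signal transducer of activin and TGF-beta receptors, stood at −1.51 (adjusted p = 0.0949) and Id4 at −1.90 (adjusted p = 0.536). Camera called the list (adjusted p = 0.0165), and adjusted p = 0.736 with an estimated correlation. It was not called without Control 2 (0.198) or LDKO 1 (0.413). The 24 denervation and regeneration genes had a median of 0.14, and Myh3 rose over all genes and when adjusted over the list alone. That list was called at adjusted p = 0.0469, with adjusted p = 0.736 under an estimated correlation. The call was lost without Control 2 (0.459), LDKO 1 (0.154) or LDKO 2 (0.124). Energy dissipation genes (25 tested) had a median of −0.02 with 0 passing over all genes, and 1 higher and 2 lower when adjusted over the list alone. Their examples were the mitochondrial carrier Slc25a25 at −2.20 (adjusted p = 0.261), the coactivator Ppargc1a at −1.25 (adjusted p = 0.464) and the calcium pump regulator Sln at 1.5 (adjusted p = 0.469). Camera did not call them (adjusted p = 0.397). In all, 11 lists were called and 14 were not (adjusted p from 0.0985 to 0.982), and 4 of the 11 were called with each of the 6 libraries left out.

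LTKOFstL/L against Control asks what differs in muscle when the liver lacks Fst together with both substrates. The zinc transporter gene Slc39a7 rose by log2 4.78 ± 0.47 (SE, n = 2 per group, adjusted p = 0.00273), and Cish, a feedback inhibitor of cytokine signalling, rose by 4.15 ± 0.40 (adjusted p = 0.0023). Fatty acid synthase, Fasn, rose by 3.69 ± 0.64 (adjusted p = 0.0405), and its values were 4.62 and 2.35 in the LTKOFstL/L libraries. The Fasn call was lost without Control 1 (change 3.41) or Control 2 (3.97). It was also lost with a single prior (adjusted p = 0.16), no level filter (0.081) and the replicate block (0.0879). With only the groups compared, which equals leaving out an LDKO library, it was lost too (0.244). It stood with a spline trend (0.000113). The largest other named rises were in Tenm4 (3.31), the adipocyte hormone gene Retn (3.29), the clock output factor Dbp (3.13), the potassium channel gene Kcnh2 (2.99), Tmem45b (2.77), the interferon-inducible Ifi27l2a (2.76) and Fbxo44 (2.69). Acot1, an acyl-CoA thioesterase, fell by 3.35 ± 0.21 (adjusted p = 0.000292), and Aarsd1 fell by 4.04 ± 0.18 (adjusted p = 3.12e-05). Fam131c (−5.38), the antisense transcript Plet1os (−4.88) and the fatty acid hydroxylase Cyp4a14 (−4.45) fell too. The other falls named by the rule were the acinar genes Amy2a5, Cpa1, Cela3b, Ctrl and Cela1, between −13.63 and −9.64, and 26 of 26 acinar genes were lower. Reads may be shared between Acot1 and Acot2, between Cyp4a14 and its paralogues, and between overlapping genes at Plet1os and Aarsd1.

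In total 342 genes passed in LTKOFstL/L against Control, 138 higher and 204 lower, 282 of them with at least a 2-fold change, and 2476 had an unadjusted p under 0.05. With the acinar genes left out of the fit 259 passed, 116 higher and 143 lower. The small p-values of the acinar genes thus let other genes pass the adjustment as well, rises among them. Left-out libraries gave 72 genes without Control 1, 171 without Control 2, 611 without either LDKO library, 88 without LTKOFstL/L 1 and 103 without LTKOFstL/L 2, and other settings gave 32 with a single prior, 101 with no level filter, 611 with only these groups, 175 with a spline trend and 604 at a threshold of 0.10. Of the 46 named genes that passed, 15 still passed without Control 1, 25 without Control 2, 44 without either LDKO library, 19 without LTKOFstL/L 1 and 26 without LTKOFstL/L 2, and 2 with a single prior, Acot1 and Aarsd1.

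Of 28 atrophy and FoxO genes 6 fell, and adjusted over the list alone 17 were lower and 1 higher, with a median log2 change of −0.86. They included the ubiquitin ligase genes Fbxo32, which fell by 2.15 ± 0.22, and Trim63, which fell by 2.48 ± 0.32. The autophagy gene Gabarapl1 fell by 1.86 ± 0.16, and the growth inhibitor Ddit4 fell by 2.95 ± 0.35. The atrophy list was called by camera (adjusted p = 2.14e-10), and adjusted p = 0.736 with an estimated correlation. Of 31 fatty acid oxidation genes 4 fell, 5 adjusted over the list alone, with a median of −0.16. Among them were Acot1, its mitochondrial relative Acot2 (−2.12) and the lipid droplet protein gene Plin5 (−0.79). Camera gave adjusted p = 0.00675, and adjusted p = 0.736 with an estimated correlation. Of 24 immediate early and heat shock genes 5 fell, and adjusted over the list alone 7 were lower and 1 higher, among them Maff (−2.67), Jun (−1.45), Fosl2 (−2.10) and Nr4a1 (−1.47). The median was −0.31, and the list was called at adjusted p = 0.00222, with adjusted p = 0.736 under an estimated correlation.

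Lipid synthesis and fat cell lists had higher medians in LTKOFstL/L. Of 24 lipid synthesis genes 3 rose, and adjusted over the list alone 6 were higher and 1 lower, with a median of 0.50. Fasn, the lipase-like gene Pnpla3 (2.51) and the lipogenic regulator Thrsp (1.97) rose. Camera called the list (adjusted p = 0.00159), and adjusted p = 0.736 with an estimated correlation. Beside them, all 12 adipocyte markers had higher means than in Control, with a median of 1.21. Retn rose, 7 of the 12 were higher when adjusted over the list alone, and adiponectin, Adipoq, stood at 2.07 (adjusted p = 0.0543). The Retn call was lost without Control 1 (0.147), Control 2 (0.06) or LTKOFstL/L 1 (0.0817), where its change was 2.50. The adipocyte list was called (adjusted p = 1.65e-05), and adjusted p = 0.736 with an estimated correlation. Of 29 extracellular matrix genes 3 rose, and adjusted over the list alone 16 were higher and 6 lower, with a median of 0.74. The rises were the collagens Col3a1 (1.79) and Col5a1 (1.26) and the matrix protein Sparc (0.87). Camera called the matrix list (adjusted p = 0.000623), and adjusted p = 0.736 with an estimated correlation.

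Among 38 insulin and IGF signalling genes, the IGF-binding protein gene Igfbp5 rose by 2.64 ± 0.23 from Control to LTKOFstL/L. Tbc1d4, a regulator of insulin-stimulated glucose transport, fell by 1.96 ± 0.19, and Irs2 fell too. Adjusted over the list alone 5 were higher and 2 lower, and camera did not call the list (adjusted p = 0.852). Of 14 fast fibre genes Casq1, the fast muscle calsequestrin, rose by 0.84 ± 0.15 (median 0.14, 1 higher adjusted over the list alone). Camera gave that list adjusted p = 0.116, and called it without LTKOFstL/L 1 (0.049). In the denervation list Myh3 rose (1.07), and the myogenic factors Myog (−2.70) and Myf6 (−0.99) fell, over all genes and adjusted over the list alone, and camera gave adjusted p = 0.646. Oxidative phosphorylation genes (median 0.17, 0 passing either way) were called at adjusted p = 0.0158, with adjusted p = 0.901 under an estimated correlation. That call was lost without Control 2 (0.373) or LTKOFstL/L 2 (0.727). Hepatocyte markers (14 tested, median −0.78, 1 lower adjusted over the list alone) were called at adjusted p = 0.0021, with adjusted p = 0.754 under an estimated correlation. They were not called without Control 2 (0.271) or LTKOFstL/L 1 (0.0894). Schwann cell and nerve markers (median −0.40, 1 lower adjusted over the list alone) were called at adjusted p = 0.0177, with adjusted p = 0.794 under an estimated correlation, and not without Control 1 (0.334) or LTKOFstL/L 2 (0.406). In all, 9 lists were called and 16 were not (adjusted p from 0.0502 to 0.962), and 6 of the 9 were called with each of the 6 libraries left out.

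LTKOFstL/L against LDKO asks what hepatic Fst loss adds on the background without both substrates. Trim63, a muscle ubiquitin ligase gene raised in wasting, fell by 3.24 ± 0.32 (log2, SE, n = 2 per group, adjusted p = 0.00771), and Fbxo32, another such ligase gene, fell by 2.78 ± 0.22 (adjusted p = 0.00407). Acot1 fell by 3.82 ± 0.21 (adjusted p = 0.00157). Slc39a7 rose by 4.51 ± 0.47 (adjusted p = 0.00703), Fasn by 3.70 ± 0.64 (adjusted p = 0.0352) and Igfbp5 by 3.31 ± 0.23 (adjusted p = 0.00254). Without LDKO 1 (change 3.56) or LDKO 2 (3.85) the Fasn call was lost. The same held with a single prior (adjusted p = 0.142), no level filter (0.062) and the replicate block (0.0781). With only the groups compared, which equals leaving out a Control library, it was lost too (0.0583). It stood with a spline trend (0.00016). Other rises were in the nicotinamide riboside kinase gene Nmrk2 (3.5), Retn (3.20), Kera (3.14), the melanocortin receptor accessory gene Mrap (3.05), the antisense transcript Irx3os (3.04) and Cish (2.93). Further falls were in Fam131c (−5.98), Plet1os (−4.38), Aarsd1 (−4.14), Klhl38 (−2.90), Sesn1 (−2.87) and Tmem140 (−2.68).

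In total 410 genes passed in LTKOFstL/L against LDKO, 192 higher and 218 lower, 313 of them with at least a 2-fold change, and 3094 had an unadjusted p under 0.05. Left-out libraries gave 263 genes without either Control library, 697 without LDKO 2, 48 without LTKOFstL/L 1 and 66 without LTKOFstL/L 2, and other settings gave 61 with a single prior, 212 with no level filter, 263 with only these groups, 267 with the replicate block, 169 with a spline trend and 956 at a threshold of 0.10. Of the 50 named genes that passed, 41 still passed without either Control library, 37 without LDKO 1, 45 without LDKO 2, 15 without LTKOFstL/L 1 and 19 without LTKOFstL/L 2, and Aarsd1, Acot1, Acot2, Fam131c, Fbxo32, Gabarapl1, Gm6472, Igfbp5, Plet1os, Tbc1d4 and Tmem140 passed in all 6 of these fits. Not counting the acinar genes, but with the adjusted p of the full fit, 188 genes passed in both LTKOFstL/L comparisons in one direction, 85 higher and 103 lower.

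**Figure D2:**
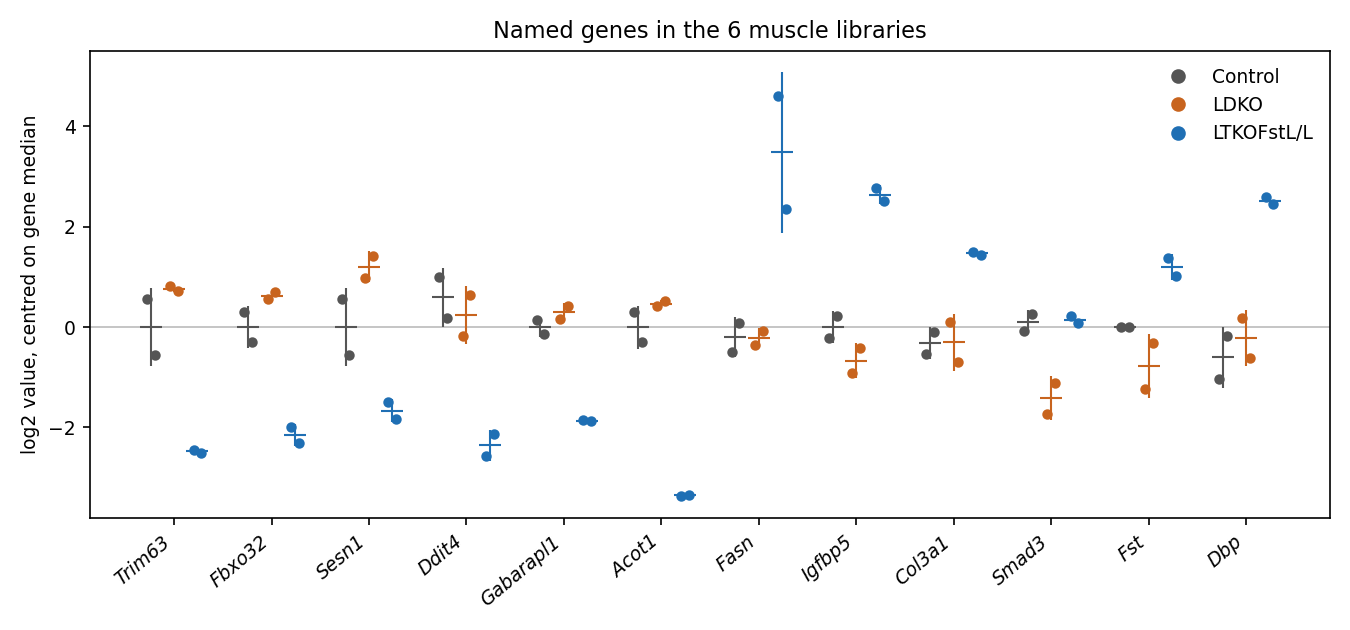
Centred log2 values of 12 named genes in the 6 libraries by genotype, with points for libraries, a dash for the mean and a line for the SD (n = 2). Trim63 lies at −2.45 and −2.51 in the LTKOFstL/L libraries and between −0.55 and 0.82 in the others.

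Of 28 atrophy and FoxO genes 14 fell from LDKO to LTKOFstL/L, 21 adjusted over the list alone, with a median log2 change of −1.25. Beside Trim63, Fbxo32 and Sesn1, Gabarapl1 fell by 2.16 ± 0.16. Camera called the list (adjusted p = 5.94e-14), and adjusted p = 0.736 with an estimated correlation. Of 31 fatty acid oxidation genes 4 fell, 9 adjusted over the list alone, with a median of −0.39, and they were Acot1, Acot2 (−2.44), Plin5 (−1.35) and the malonyl-CoA decarboxylase gene Mlycd (−0.85). That list was called at adjusted p = 5.19e-07, with adjusted p = 0.736 under an estimated correlation. Of 14 slow fibre genes Casq2 (−1.03) and the slow troponin gene Tnnt1 (−1.14) fell, 6 adjusted over the list alone, with a median of −0.49. The slow fibre list was called at adjusted p = 6.53e-05, with adjusted p = 0.736 under an estimated correlation. The fast fibre median was 0.02, with Casq1 higher by 0.94 ± 0.15 both over all genes and adjusted over the list alone, and camera adjusted p = 0.385; the list was called without LDKO 1 (0.0192).

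Of 29 extracellular matrix genes 9 rose from LDKO to LTKOFstL/L. The median was 0.86, with 18 higher and 2 lower adjusted over the list alone. Col15a1 rose by 2.06 ± 0.30, Col1a2 by 1.33 ± 0.19, Col3a1 by 1.77 ± 0.28 and Sparc by 0.90 ± 0.14. Camera called the list (adjusted p = 4.56e-06), and adjusted p = 0.736 with an estimated correlation. Of 11 fibroblast and tendon markers, which overlap in kind with it, Kera and Tnmd (1.74) rose, 3 adjusted over the list alone, with a median of 0.34. That list was called at adjusted p = 0.00308, with adjusted p = 0.736 under an estimated correlation, and not without LDKO 2 (0.111). Of 24 lipid synthesis genes Fasn, Pnpla3 (2.43) and the carbohydrate-responsive factor gene Mlxipl (0.78) rose. The median was 0.64, with 9 higher and 2 lower adjusted over the list alone. The list was called at adjusted p = 0.00101, with adjusted p = 0.736 under an estimated correlation, and not without LDKO 1 (0.0917). Beside it, all 12 adipocyte markers had higher means, with a median of 1.53. Retn rose, and 6 were higher adjusted over the list alone. The Retn call was lost without LDKO 1 (0.0716) or LTKOFstL/L 1 (0.101), where its change was 2.40. The adipocyte list was called at adjusted p = 0.000623, with adjusted p = 0.736 under an estimated correlation, and not without LTKOFstL/L 1 (0.0778).

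Among 39 genes of activin, myostatin and BMP signalling, Smad3 rose by 1.57 ± 0.23 from LDKO to LTKOFstL/L together with Fst, and 4 were higher adjusted over the list alone. Camera did not call the list (median 0.31, adjusted p = 0.0999), and did so without LDKO 2 (0.00874) or LTKOFstL/L 2 (0.0254). Of 38 insulin and IGF signalling genes Igfbp5 and the hexokinase gene Hk2 (0.85) rose and Tbc1d4 fell by 2.10 ± 0.19. Adjusted over the list alone 4 were higher and 3 lower, and camera gave adjusted p = 0.438. Hk2 was also the 1 rise among 25 tested glycolysis and glycogen entries (median 0.15, 2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0999), and that list was called without LTKOFstL/L 1 (0.049). Of 25 energy dissipation genes Ucp1, the uncoupling protein gene of brown fat, rose by 5.16 ± 1.27. Its LTKOFstL/L values were unequal, at 4.31 and 0.45. That SE comes from variances pooled over genes, and the SD of Ucp1 was 2.73 in LTKOFstL/L. The Ucp1 call stood without LTKOFstL/L 2 (change 7.1) and was lost without LDKO 1 (5.59), LDKO 2 (4.73) or LTKOFstL/L 1 (3.23). It was also lost with only the groups compared (adjusted p = 0.0897), the fit that leaving out a Control library gives. Of the energy dissipation genes 2 were higher and 1 lower adjusted over the list alone, and camera gave that list adjusted p = 0.0964 (0.0447 without LTKOFstL/L 2). Beside Ucp1, all 12 adipocyte markers had higher means (median 1.53). Of 19 clock genes Dbp (2.74) and Bhlhe41 (1.96) rose and 4 fell, among them Nfil3 (−1.42). Adjusted over the list alone 6 were higher and 5 lower, and camera gave adjusted p = 0.749. In the interferon list (27 tested) Ifi27l2a rose by 2.28 ± 0.31 (2 adjusted over the list alone, median 0.36). The list was called at adjusted p = 0.00365, with adjusted p = 0.736 under an estimated correlation, and not without LDKO 2 (0.0663). Beside it, macrophage and leukocyte markers (18 tested, 0 passing either way, 13 with higher means) had a median of 0.34 and camera adjusted p = 0.064, and were called without LDKO 1 (7.18e-05).

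Immediate early and heat shock genes (24 tested) had a median of −0.46 in LTKOFstL/L against LDKO, and Maff fell (−1.80). In this list 2 were higher and 7 lower adjusted over the list alone. It was called at adjusted p = 0.0387, with adjusted p = 0.736 under an estimated correlation. Without Control 1 (0.0512), Control 2 (0.0644), LDKO 2 (0.246), LTKOFstL/L 1 (0.0717) or LTKOFstL/L 2 (0.119) it was not called. Smooth muscle and pericyte markers (10 tested, median 0.30, 1 higher adjusted over the list alone) were called at adjusted p = 0.0158, with adjusted p = 0.736 under an estimated correlation, and not without LDKO 2 (0.118) or LTKOFstL/L 1 (0.163). Hepatocyte markers (14 tested, median −0.66, 0 passing either way) were called at adjusted p = 0.0158, with adjusted p = 0.806 under an estimated correlation, and not without LDKO 2 (0.249) or LTKOFstL/L 1 (0.239). The 38 cytosolic ribosomal protein genes (median −0.22, 0 passing either way) were called at adjusted p = 0.0158, with adjusted p = 0.901 under an estimated correlation. That call was lost without LTKOFstL/L 1 (0.501), and its direction reversed without LDKO 1 (0.604). Stress response genes (24 tested, median 0.04, adjusted p = 0.909), red blood cell markers (6 tested, median 0.20, adjusted p = 0.331) and endothelial markers (12 tested, median −0.06, adjusted p = 0.896) were not called in LTKOFstL/L against LDKO and had 0 passing members either way. Red blood cell markers were called without LDKO 1 (0.0364). In all, 12 lists were called and 13 were not (adjusted p from 0.064 to 0.909), and 4 of the 12 were called with each of the 6 libraries left out. Over the 3 comparisons, leaving out 1 library also gave 25 calls in 19 of the 43 set tests that were not called.

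**Figure D3:**
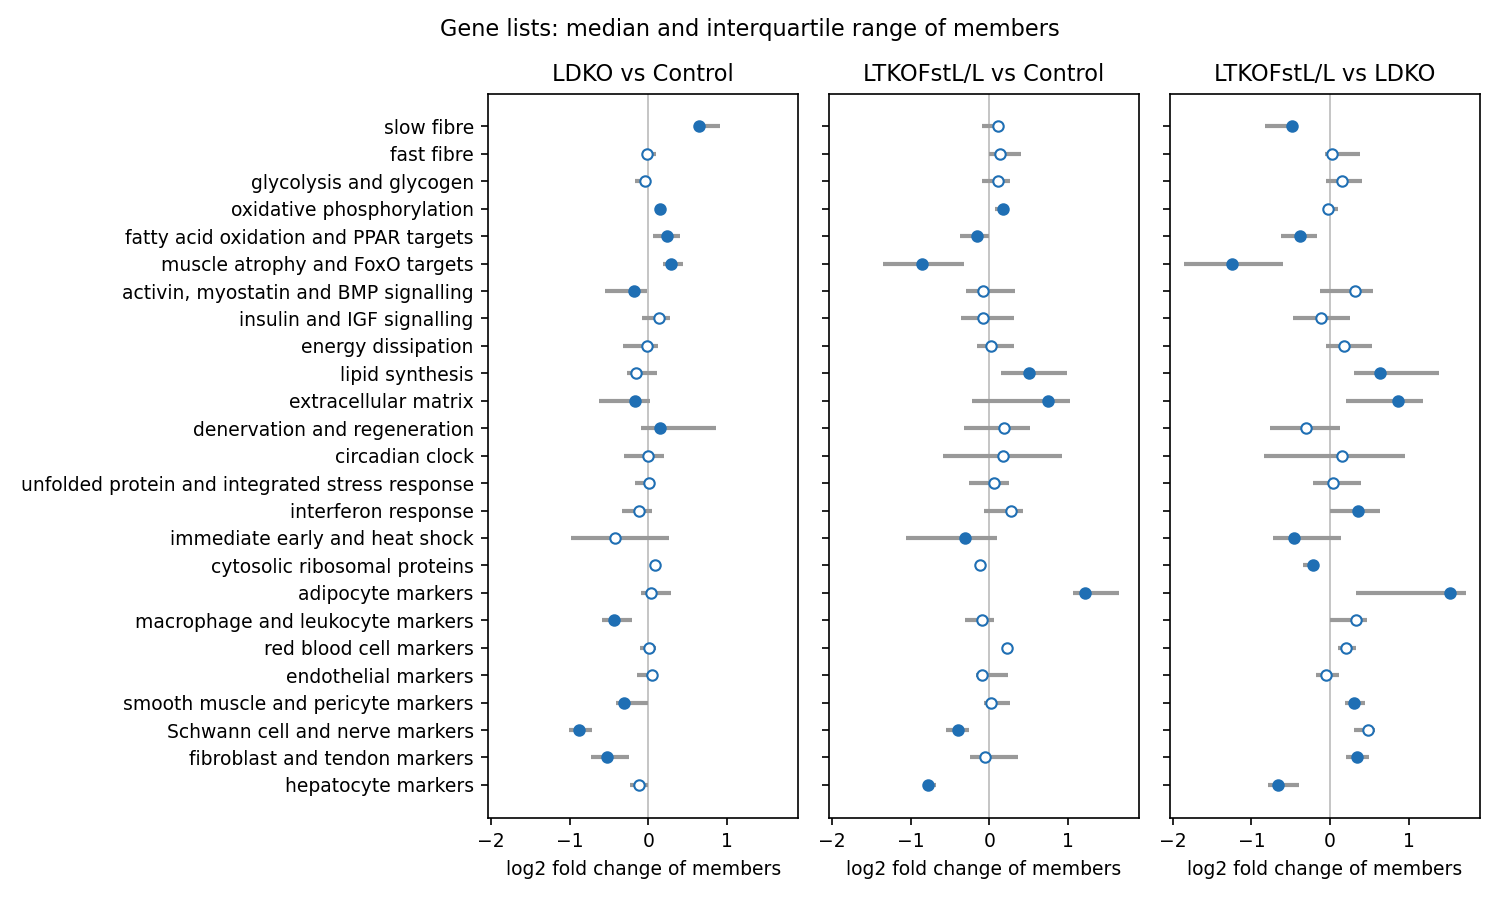
Median log2 change of each gene list in the 3 comparisons, with a line for the interquartile range of its members and filled points where the camera adjusted p was under 0.05. The atrophy and FoxO list lies at 0.29, −0.86 and −1.25 in LDKO against Control, LTKOFstL/L against Control and LTKOFstL/L against LDKO.

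The series also asks which LDKO changes depend on hepatic Fst. Genes that passed in LDKO against Control and, with the opposite sign, in LTKOFstL/L against LDKO numbered 6, and 1 passed in both with the same sign. Casq2 (ENSMUSG00000027861, chromosome 3, 102086415 to 102146514) rose by 1.06 ± 0.14 and then fell by 1.03 ± 0.14. Chad (ENSMUSG00000039084, chromosome 11, 94565047 to 94569127) fell by 1.79 ± 0.19 and then rose by 1.37 ± 0.19. BC048679 rose by 1.65 and then fell by 1.22, and the pseudogenes Gm6472 (4.34, then −4.07) and Gm16505 (2.01, then −1.51) followed the same course. With the acinar genes left out of the fit the count was 4, and Casq2 and Gm16505 were lost. Gm6472 passed in both comparisons whichever library was left out, while Gm16505 passed in neither once a library was left out. Each of the other genes lost a call in some or all of these fits. The microRNA gene model Gm44364 was at the floor in both LDKO libraries and above it in the others. Independent lists would share 0.08 genes in the direction up then down and 0.471 in the direction down then up. Both comparisons use the LDKO libraries, and 100 simulated tables without change gave a mean of 0.24 and at most 4 such genes. Those tables held independent genes and no change in any group. They do not show how many genes the shared libraries would give beside real, unrelated changes, so the observed count is not judged by them. The correlation of both changes across genes was −0.274, against a simulated mean of −0.501 from the shared libraries alone. Their covariance was −0.141, against a simulated −0.112, a difference of −0.028. The acinar genes, high in Control, are included in this covariance and in those of the split below. Their median was lower in LTKOFstL/L (−1.77 and −1.68) than in LDKO (0.89 and −1.32). Large changes of the same sign pull a covariance upward, by an amount that was not computed. The covariances therefore do not show how far the other genes moved back. Genes are not independent replicates. The LDKO libraries also differ from the others in scaling and in the share of whole reads, which cannot be told apart from genotype here. A split that leaves 1 LDKO library in each comparison, chosen after seeing the data, gave covariances of −0.013 (LDKO 1 against Control, LDKO 2 against LTKOFstL/L) and −0.001 (the other way round). It gave 15 and 7 genes with opposite signs and 5 and 2 with the same sign, and 4 of the 6 genes were among them each time. With 1 LDKO library in a comparison the spread comes from the other groups, and part of the overlap of the unsplit comparisons may come from the shared libraries. The count was 0 with a single prior, 1 with no level filter, 12 with a spline trend and 11 at a threshold of 0.10, and left-out libraries gave 1 without Control 1, 2 without Control 2, 10 without LDKO 1, 73 without LDKO 2, 3 without LTKOFstL/L 1 and 1 without LTKOFstL/L 2.

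LDKO against the mean of both other genotypes can pass through a difference from either genotype or from both. The contractile genes Myh6, the cardiac alpha myosin (1.61 ± 0.20, SE), Myh3 (1.35 ± 0.16) and Casq2 (1.05 ± 0.12) were higher in LDKO than this mean, as were Trim63 (2.01), Fbxo32 (1.70) and Plin5 (0.95). Trim63, Fbxo32 and Plin5 did not pass in LDKO against Control (adjusted p of 0.738, 0.672 and 0.507) and fell from Control to LTKOFstL/L. Lower in LDKO were Smad3 (−1.54 ± 0.20), the Wnt antagonist gene Sfrp2 (−1.73 ± 0.26) and Chad (−1.58 ± 0.17), with the contrast testing 2 LDKO libraries against 4 others. Myh6 (adjusted p = 0.0528), Smad3 (0.0949) and Sfrp2 (0.132) did not pass in LDKO against Control either, and Myh3 did not in LTKOFstL/L against LDKO (0.0704). These examples were chosen after their values were seen. In total 68 genes passed, 31 higher and 37 lower, 63 of them with at least a 2-fold change. Of the 37, 15 were on the acinar list, whose Control values are high. Klk1, Tff2 and Dmbt1, also among the 37, are not on the list but have the same Control profile. Both LDKO libraries lay outside the 4 others in 43 of the 68 (26 above and 17 below). The contrast selects for this, so the share is no separate evidence. Over all tested genes it held for 17.4%, against 13.3% if the libraries were exchangeable. The LDKO libraries also differ from the others in scaling, so they may not be exchangeable, and this cannot be told apart from genotype. The count was 4 with a single prior, 6 with no level filter and 178 at a threshold of 0.10, and left-out libraries gave 39 without Control 1, 8 without Control 2, 213 without LDKO 2, 6 without LTKOFstL/L 1 and 9 without LTKOFstL/L 2.

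The deposited lists from the authors' test hold 1378 genes for LDKO against Control (621 higher and 757 lower), 2176 for LTKOFstL/L against Control (1031 and 1145) and 2421 for LTKOFstL/L against LDKO (1182 and 1239). Of these, 697, 1258 and 1430 were among the genes tested here, and 46, 282 and 313 passed here with the same sign. The authors' lists hold only changes of at least 2-fold, a bound not used for the calls here. Calls here with at least a 2-fold change numbered the same 46, 282 and 313. The 919 genes that the authors list for LDKO but not for LTKOFstL/L against Control (466 higher and 453 lower) include 438 tested here, of which 6 passed in LDKO against Control. All samples being the ones analysed here, these overlaps are not independent evidence.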

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

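The tests with a spline trend, no robust moderation, a level of at least 8, no acinar genes and 1 LDKO library per comparison were chosen only after the results were seen, and so were the level strata of the reported fit; the other alternatives were planned. Counts are given in the order LDKO against Control, LTKOFstL/L against Control, LTKOFstL/L against LDKO, LDKO against both, and moved back, as reported 46, 342, 410, 68 and 6. A single prior gave 1, 32, 61, 4 and 0 (unadjusted p under 0.05 in 1052, 2283, 2773 and 1878 genes); no level filter gave 2, 101, 212, 6 and 1; a threshold of 0.10 gave 52, 604, 956, 178 and 11. Only the groups compared gave 41, 611 and 263. The replicate numbers cross nothing in the labels, and within-group differences correlate across genes at 0.175, −0.037 and −0.163; the block gave 47, 244, 267, 56 and 5. The spline gave 54, 175, 169, 81 and 12, sharing 28, 97, 85 and 15 genes with the reported calls, a level of at least 8 gave 28, 271, 396, 54 and 4, and no acinar genes gave 19, 259, 413, 46 and 4. No robust moderation (48, 346, 431, 76 and 6) and median rescaling, which shifts libraries by 0.0085 to 0.0103 and so tests little (46, 343, 411, 66 and 6), stayed within 1.5 times. With 1 library left out the ranges were 3 (without Control 1) to 131 (without LDKO 2), 72 (without Control 1) to 611 (without either LDKO library), 48 (without LTKOFstL/L 1) to 697, 6 (without LTKOFstL/L 1) to 213 and 1 (without Control 1 or LTKOFstL/L 2) to 73 (without LDKO 2 in these last 3). With 1 LDKO library in each comparison and none shared, genes moved back numbered 15 and 7. Called lists numbered 32, 25 to 35 with 1 library left out, 30 with the block, 0 with an estimated correlation and 0 with fry. Reversed in direction, without a call, were oxidative phosphorylation in LDKO against Control without LDKO 1 (range 2.65e-05 to 0.803), ribosomal proteins in LTKOFstL/L against LDKO without LDKO 1 (1.36e-06 to 0.604) and extracellular matrix in LDKO against Control without LDKO 2 (4.51e-06 to 0.996); the highest adjusted p is the reversed one. Of 107 passing results for named genes in 351, those still passing with a single prior were 0 of 11, 2 of 46 and 9 of 50, and with the spline 7, 20 and 18. Fewer genes tested or fewer libraries go with some of these shifts; otherwise the cause was not tested. Another pseudocount was not run, since the values are centred logarithms. Genes near the floor varied more: the median SD within groups is 0.898 at a log2 level of 1 to 2 and 0.166 at 8 to 16. Whether depth sets this was not tested.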

Other observations

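The tests of acinar carry-over, of fewer muscle fibres, of fewer slow fibres and of clustering on the genome were chosen only after the results were seen, while those of islets and of time of day were set before their genes were looked up, apart from Dbp, Nfil3 and the clock list median. The genes of this paragraph were likewise chosen after their values were seen. Amd1 and Amd2, which encode the decarboxylase that supplies polyamine synthesis, were higher in LTKOFstL/L than in LDKO by 2.03 ± 0.19 (SE, adjusted p = 0.00604) and 2.01 ± 0.16 (adjusted p = 0.00407), in both libraries of each group. Their sequences are close, so their reads are not independent. Smox, the spermine oxidase gene, was higher by 1.45 ± 0.20 (adjusted p = 0.0192). Part of each difference is a low LDKO value, at −1.15 (Amd1), −1.08 (Amd2) and −0.96 (Smox) against Control, none passing. From Control to LTKOFstL/L Amd2 rose (0.93, adjusted p = 0.0385), while Amd1 (0.89, 0.0721) and Smox (0.49, 0.316) did not pass. The acetate-activating enzyme gene Acss1 fell by 2.08 ± 0.17 from LDKO to LTKOFstL/L (adjusted p = 0.00407). Rsc1a1 (chromosome 4, 141683851 to 141685599) was listed at 0 in the 4 Control and LDKO libraries and at 7.85 and 8 in LTKOFstL/L. It lies inside Ddi2 (141677549 to 141723419), which fell by 1.37 ± 0.20 from Control to LTKOFstL/L (adjusted p = 0.0239).

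Pancreatic acinar transcripts were high in both Control libraries. Their log2 level could be recovered for 19 of 26 genes, with a median of 14.68 in Control 1 and 10.79 in Control 2, and the highest was 17.33 for Ctrb1. Carried-over acinar cell RNA predicts that all genes keep one ratio between these libraries, and the SD of that difference over the 26 genes, listed after their values were seen, was 0.199 around a median of 4.07. RNA of acinar cells carried over into both Control samples may therefore explain the pattern, although this does not separate one source from several, and no biological explanation was tested. Whole pancreas would bring islets as well. Only 2 of 10 detected islet genes, Ins1 and Ins2, exceeded the other groups by 2 in Control 1. Fewer than 3 had been set in advance as the outcome against islets. That reading was changed after the result was seen, because Ins2 reached a log2 level of only 3.67 there. Rarer islet genes thus had no room to reach the bound, and whether islets came along cannot be told.

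Atrophy and FoxO genes were lower in LTKOFstL/L than in LDKO, with a median of −1.25. A lower share of all muscle fibres would lower fast fibre genes alike, and their median of 0.024 (SE of the mean 0.091) lies far above −0.626, the bound set at 0.5 of the atrophy median, which argues against it. A lower share of slow fibres alone would lower slow fibre genes at least as much, and their median of −0.49 (SE of the mean 0.088, all 14 genes lower) lies far above −1.25, and against Control it was 0.11 beside −0.86 for the atrophy list, which argues against that share as the cause of the pattern. Another time of day at tissue collection could contribute: the positive limb of the clock had a median of −1.132 (4 genes, SE of the mean 0.351) and the Dbp and Rev-erb limb one of 0.625 (9 genes, SE of the mean 0.323), the opposite shifts it predicts; of these 13 genes only Dbp, Nfil3 and Per1 passed, Per1 against its limb (−0.80 ± 0.14, adjusted p = 0.0413), and neither collection times nor a link from the clock to these genes was examined. The loss of hepatic Fst itself, which the design names, stays open as an untested biological explanation.

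Genes called in both LTKOFstL/L comparisons would cluster on the genome if strain DNA around the floxed gene had come with the genotype. The fullest of 276 windows of 10 Mb, on chromosome 4 and on chromosome 7, held 6 of the 188 genes. In 10000 shuffles of the calls over tested genes the 95th percentile was 7, and 24.48% of shuffles reached 6. Chance positions are therefore enough for the fullest window of this size. Clustering over shorter distances was not tested, so it stays open. Fam131c, Slc25a34, Ddi2 and Rsc1a1, all called, lie between positions 141368220 and 141723419 of chromosome 4. The window that holds Fst had 2 called genes, which overlap each other, too few to say whether its DNA played a part.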
